A study of Rattus norvegicus with 9 samples.

How the data were processed

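MicroRNAs (miRNAs) were measured in the soleus, a postural hindlimb muscle, of male Sprague-Dawley rats aged 6 months. Control rats were set against rats whose hindlimbs had been unloaded by tail suspension for 2 or 7 days, with 3 arrays per group and 9 arrays in all. Per the labels' protocols, total RNA was treated with DNase, its mean RNA integrity number was 8.4 ± 0.5, and a service provider ran the assay from 5 µg of total RNA. The small RNA fraction was given a poly(A) tail and an oligonucleotide tag for dye staining, and hybridised to a microfluidic chip in 1 colour (Cy5). The labels describe 234 rat probes from miRBase 9.0 and 96 probes for predicted rat miRNAs. In the scanner files 238 probes carry rat miRNA names and 96 carry names of predicted miRNAs, which gives 334 miRNA probes with 9 repeat spots each among 3968 spots per array.

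Per the file headers, the deposited scanner files hold the mean brightness (intensity) of each spot on a linear scale and its standard deviation within the spot. Their columns name the probe, its target sequence, position, brightness, spread and control type, with no local background and no slide or scan batch, so no batch could be set as a block. The brightness was taken as not background-subtracted, from the values: the 614 empty spots of an array had medians between 27.4 and 53.3. The image software and background steps are not given in the sources used here. The authors' value table of the same arrays holds whole-number intensity values for 162 probes with a lowest value of 1. Its log2 values followed the log2 scanner brightness with correlations across probes of 0.945 to 0.990, which settles that its direction is the same. Such correlations cannot settle that its values are proportional to brightness, and the table was taken as linear. Its column medians ran from 306 to 403.5, and its centring stays unknown. That table was used only as an alternative.

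Analysis was run in R 4.3.3 with limma 3.58.1. Spot brightness was corrected with normexp and an offset of 50, fitted on all spots of each array. The plan had named normexp for files with a local background; its use on files without one, and the rule for combining repeat spots in the detection call, were settled after the files had been seen. Control spots were then left out, log2 values of miRNA spots were quantile normalised between arrays, and the 9 repeat spots of a probe were averaged. A probe counted as detected on an array when more than 0.5 of its spots lay above the 95th percentile of that array's empty spots. Probes detected on every array of at least 1 group were tested, 178 in all, of which 167 were named rat miRNAs and 11 predicted ones. Of the 334 probes, 143 were detected on all 9 arrays and 116 on none. Targets of 22 pairs among 32 of the tested probes differed by at most 2 bases (let-7 members, miR-1 and miR-206, miR-103 and miR-107, miR-133a and miR-133b among them), and such probes may share signal. Quantile normalisation gives the brightest probes nearly the same value on every array, so the small spread of miR-1 and miR-206 was set by that step. The highest spot brightness per array lay between 56151 and 62914.

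One mean per group was fitted to all 9 arrays with lmFit and eBayes, and the contrasts were 2 days against control, 7 days against control and 7 days against 2 days, with a moderated F test of both suspension contrasts. The test used 7.78 total degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the tested probes, with a threshold of 0.05. Errors of log2 fold changes are the moderated standard errors of that fit, and intervals are at 95%. The precision of each fold change is limited by the 3 arrays per group: the median standard error was 0.166 log2 units. The median SD between arrays of a group was 0.215, against a standard error of 0.039 for the mean of the 9 repeat spots on an array. By group that median SD was 0.174 in controls, 0.247 after 2 days and 0.117 after 7 days. The fit shares its spread across the groups. Its errors may therefore be too large for 7 days against control and too small for 2 days against control. Numbers of detected probes were compared by an exact two-sided permutation test, which with 3 arrays against 3 cannot go below p = 0.1.

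A total of 16 miRNA lists were fixed before the data were examined: striated muscle miRNAs, let-7 family, miR-17 to miR-92 clusters, the family of miR-15, miR-16, miR-103 and miR-107, miR-29 family, miR-30 family, miR-23/24/27 clusters, miR-26 and miR-181 families, myoblast and regeneration miRNAs, inflammation and fibrosis miRNAs, blood cell markers, endothelial markers, smooth muscle and fibroblast markers, nerve markers, epithelial and endocrine gland markers, and the imprinted Dlk1-Dio3 cluster. Each had at least 3 tested members. Lists were tested with limma's camera (two-sided, preset correlation of 0.01, Benjamini-Hochberg over the 16 lists), with camera at an estimated correlation and fry beside it. MiR-221 and miR-222 stand in both the endothelial and the myoblast list. Per comparison, the miRNAs named are those past the threshold, the 10 with the smallest unadjusted p where fewer than 10 passed, every tested member of the striated muscle list, and up to 4 members of each other list with the largest absolute log2 fold change. Of the miRNAs this rule gives, the text names fewer, and which ones was chosen after their values were seen. MiR-126 falls outside the rule and was named after its values were seen.

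Alternatives to each step were run one at a time: other normalisations, offsets, filters, variance estimates, array weights, the replicate number as a block, the authors' value table, and leaving out each array. Those with GC content, the empty spots as negative controls, a pseudocount of 50 on the value table, or control array 1 and 2-day array 2 left out together were chosen after seeing the data. Tested on simulated data with the spread of the 178 probes in the comparison of 7 days with control, limma recovered 49.3% of changes of 0.5 log2 units, 85.5% of changes of 1 and 98.2% of changes of 2 over 100 simulations with 10 changed miRNAs of each size. False calls made up 4.1% of its calls. All sizes were changed in the same simulated data, and probes varied independently. With fewer changed miRNAs the adjusted threshold is harder to pass, so recovery of sparse changes may be lower than these shares. In the same comparison, camera called 100% of simulated lists of 10 miRNAs shifted by 0.3 and 3% of unshifted lists at an unadjusted p under 0.05. The simulated probes varied independently of each other, whereas the estimated correlation within the tested lists reached 0.867 (let-7 family). These shares for camera therefore do not carry over to lists of correlated miRNAs. Of the 167 rat miRNA probes tested, 156 matched a gene name in the RefSeq table used, and no coordinates are printed because the array names no genome build.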

Results

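The series asked how the miRNA profile of the rat soleus differs between normally loaded muscle and muscle unloaded by hindlimb suspension, which induces atrophy, for 2 or 7 days. Each group had 3 arrays. Nothing in the labels says in so many words that the 3 replicates were separate animals, so p-values measure the spread between these samples. Arrays were closely alike, with a mean correlation of log2 intensity of 0.987 over the 9 pairs within a group and 0.986 over the 27 pairs between groups. The 95th percentile of the empty spots ran from 31.6 to 73.3 units of scanner brightness. Levels of different probes are not compared with each other, because brightness depends on the probe.

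Control arrays had 171.0 ± 13.5 miRNA probes detected (mean ± SD, n = 3). The count was 162.3 ± 14.6 after 2 days (n = 3) and 193.7 ± 9.1 after 7 days (n = 3). The 7-day arrays had 187 to 204 detected probes and lay above every array of the other groups (149 to 184). The empty-spot limit behind these counts also differed. It was 32.0 to 38.4 on the 7-day arrays, 31.6 to 53.6 on the controls and 33.7 to 73.3 after 2 days. A higher count is therefore not by itself a sign of more miRNAs expressed. An exact two-sided permutation test gave p = 0.5 for 2 days against control and p = 0.1 for both 7-day comparisons (0.15 after Benjamini-Hochberg over 3 comparisons), and 0.1 is the smallest p the design allows. At the 99th percentile of the empty spots the groups overlapped, with 161, 177 and 183 probes on the 7-day arrays, 151 to 169 on the controls and up to 173 after 2 days, and both 7-day p-values were 0.2.

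**Figure D1:**
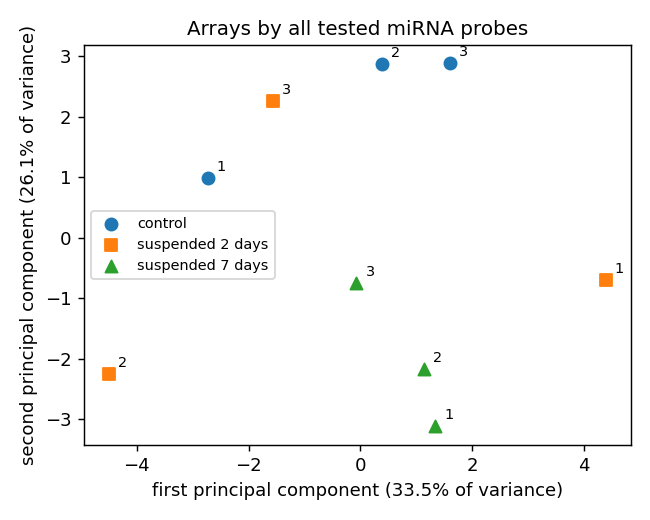
Scores of the 9 arrays on the first (x axis) and second (y axis) principal components of log2 intensity over the 178 tested miRNA probes, with symbols for the 3 groups and replicate numbers beside them. The first component (33.5% of the variance) runs from -4.5 to 4.39, both ends being 2-day arrays, while on the second (26.1%) the 7-day arrays lie between -3.12 and -0.75 and the controls between 0.98 and 2.88. Arrays with negative scores on the second component were those with log2 values of miR-126* from 11.06 to 11.86. On 2-day array 3 miR-126* was 8.74 and the score 2.26, within the range of the controls. That probe alone may carry much of the second component, and its loading there was not examined.

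After 2 days of suspension, miR-333 fell by 0.94 ± 0.13 log2 units (SE, n = 3 arrays per group; limma adjusted p = 0.017), which is 1.92-fold lower. Its mean log2 intensity was 7.24 ± 0.03 (SD) in controls and 6.30 ± 0.25 after 2 days, and each 2-day array lay below each control array. The 2-day mean was close to the mean of the lowest detected signals on those arrays (log2 6.13). At a level so near background the size of the fall is less sure than its standard error. In the authors' value table the log2 fold change was -2.08 (adjusted p = 0.0245), and over all 28 alternatives it ran from -2.08 to -0.72. It was the only miRNA of 178 past the threshold. The next smallest p-values belonged to miR-505 (log2 fold change -0.41 ± 0.08, adjusted p = 0.0599) and miR-222 (-0.54 ± 0.11, adjusted p = 0.0599), followed by miR-221 (-0.50 ± 0.12, adjusted p = 0.131). Without 2-day array 1, and with array weights, limma called miR-221, miR-222, miR-333 and miR-505, all with lower values, and miR-505 also passed with no detection filter and in the unmoderated test. MiR-221 and miR-222 are made from neighbouring genes on chromosome X and are known in muscle for their high level in proliferating myoblasts and their fall during differentiation.

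Of the other miRNAs with the 10 smallest p-values, none past the threshold, miR-189 (an older name for the second arm of a miR-24 hairpin) had a log2 fold change of 0.51 ± 0.15, miR-10a, encoded in a Hox cluster, 0.75 ± 0.27, and miR-98, a let-7 relative, 0.52 ± 0.21. MiR-17 of the miR-17 to miR-92 cluster stood at -0.39 ± 0.12. The predicted miRNA probe MM_264 stood at 0.77 ± 0.21 and miR-190, near background, at 0.17 ± 0.07. At an unadjusted p under 0.05 there were 12 miRNAs, 7 with higher and 5 with lower values, where 8.9 would be passed by chance. That count was 22 without 2-day array 1, 19 without 2-day array 3 and 7 with 75th percentile centring, and its direction was 8 of 9 higher with median centring and without normalisation, 6 of 7 with 75th percentile centring and 2 of 10 without control array 3. The call of miR-333 ended with median centring (log2 fold change -0.80, adjusted p = 0.374), 75th percentile centring (-0.84, adjusted p = 0.521) and no normalisation between arrays (-0.72, adjusted p = 0.0927), and with only the 6 arrays of both groups (adjusted p = 0.132). It also ended without control array 1 (adjusted p = 0.0919), 2 (0.0959) or 3 (0.112), without 2-day array 2 (0.0929) or 3 (0.0775), or without 7-day array 2 (0.0547), the log2 fold change staying between -0.95 and -0.86.

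The miRNAs that define striated muscle showed no call at either time. MiR-1, miR-133a and miR-133b, which act in muscle differentiation and growth, had log2 fold changes at 2 days of -0.01 ± 0.06, -0.09 ± 0.11 and -0.05 ± 0.11. At 7 days they stood at -0.02 ± 0.06, -0.12 ± 0.11 and -0.11 ± 0.11. MiR-206, typical of slow and regenerating muscle and a neighbour of miR-133b, stood at 0.01 ± 0.06 and 0.02 ± 0.06. MiR-499, which lies within a myosin heavy chain gene and belongs to the slow-fibre programme, stood at -0.09 ± 0.07 and -0.08 ± 0.07. Its 95% interval at 7 days ran from -0.24 to 0.08. MiR-1*, the second arm of the miR-1 hairpin, had 0.44 ± 0.19 at 2 days and 0.10 ± 0.19 at 7 days at a level near background. MiR-208, detected on 2 control arrays, no 2-day array and all 7-day arrays, had 0.06 ± 0.15 and -0.14 ± 0.15, also at a level near background. Over the alternatives miR-1, miR-133a, miR-133b, miR-206 and miR-499 lay between -0.22 and 0.05 at 2 days and between -0.39 and 0.06 at 7 days, miR-1* between -0.29 and 0.27 at 7 days, and miR-208 between -0.11 and 0.26 at 2 days and between -0.57 and -0.09 at 7 days. The list of 7 had a median log2 fold change of -0.01 at 2 days (camera adjusted p = 0.785) and -0.08 at 7 days (adjusted p = 0.467), with means of 0.04 and -0.05, so that median and mean differed in sign at 2 days. Quantile normalisation nearly fixes the brightest probes, miR-1 and miR-206 among them: with median centring, which moved the median of all tested miRNAs at 7 days from -0.03 to -0.21, the list's median at 7 days was -0.31, and without normalisation it was 0.04 beside 0.14 for all miRNAs.

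No list shifted past the threshold at 2 days by camera, whose smallest adjusted p was 0.103, or with an estimated correlation or fry's one-directional test, while 3 lists had an unadjusted p under 0.05. Those 3 were the miR-17 to miR-92 clusters (8 of 9 members with lower values, median -0.26, adjusted p = 0.103), the myoblast list (8 of 11 lower, median -0.14, adjusted p = 0.106) and the endothelial list (5 of 6 lower, median -0.19, adjusted p = 0.106). The endothelial list's mean was 0.01, against its median and test, because miR-126* stood at 1.58 ± 0.70 (2.38 without 2-day array 3, and 5.03 in the authors' value table, or 3.04 there with a pseudocount of 50). Adjusted over the list alone, miR-221 and miR-222 passed in the myoblast and the endothelial list and no member passed in the other 14. Fry's test for change in either direction, which does not compare a list with other miRNAs, called both of these lists (adjusted p = 0.0031 each). The other 13 lists had camera adjusted p-values from 0.327 to 0.885 and medians from -0.50 (blood cell markers, 3 of 3 lower) to 0.05 (let-7 family, 7 of 9 higher). Without normalisation between arrays the medians of the miR-17 to miR-92 clusters, the myoblast and the endothelial list were -0.04, 0.00 and -0.04 beside 0.07 for all miRNAs. Without control array 1, camera called the miR-17 to miR-92 clusters lower (adjusted p = 0.00396). Leaving out 2-day array 1 gave 3 calls (the miR-29 family higher, the myoblast and inflammation lists lower) and leaving out 2-day array 3 gave 2 (the let-7 family higher, the miR-17 to miR-92 clusters lower). None of these calls passed with an estimated correlation, where the adjusted p-values were 0.436 to 0.895. MiR-20a, of that cluster, had -0.35 ± 0.16.

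After 7 days, limma called 0 of 178 miRNAs, with 25 at an unadjusted p under 0.05 (13 with higher and 12 with lower values) where 8.9 would be passed by chance. That count was 10 without 7-day array 2, 14 without 7-day array 1, 15 without control array 1 and 16 without control array 2. Its direction depended on the scaling, with 7 of 19 higher with median centring, 6 of 20 with 75th percentile centring and 27 of 28 without normalisation. The smallest p-values belonged to miR-222 (log2 fold change -0.61 ± 0.11, adjusted p = 0.0874) and miR-221 (-0.60 ± 0.12, adjusted p = 0.0946), which were 1.52-fold and 1.51-fold lower, with each of the 3 arrays below each control array. MiR-126*, the second arm of the hairpin that gives the endothelial miR-126, had the largest fold change, 7.24-fold higher (log2 2.86 ± 0.70, adjusted p = 0.138). Its mean log2 intensity was 8.77 ± 0.88 in controls, 10.35 ± 1.39 after 2 days and 11.62 ± 0.40 after 7 days (SD, n = 3 each). In the authors' value table, which holds its lowest value, 1, for miR-126* on control array 1, the log2 fold change was 6.41, or 4.36 with a pseudocount of 50. MiR-126 itself stood at 0.00 ± 0.08, with a 95% interval from -0.17 to 0.18 under quantile normalisation, which compresses bright probes. With median centring it stood at -0.18 (-0.71 to 0.35) and without normalisation at 0.17 (-0.13 to 0.47). MiR-333 stood at -0.54 ± 0.13 and miR-148b at 0.76 ± 0.18 (both adjusted p = 0.138).

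**Figure D2:**
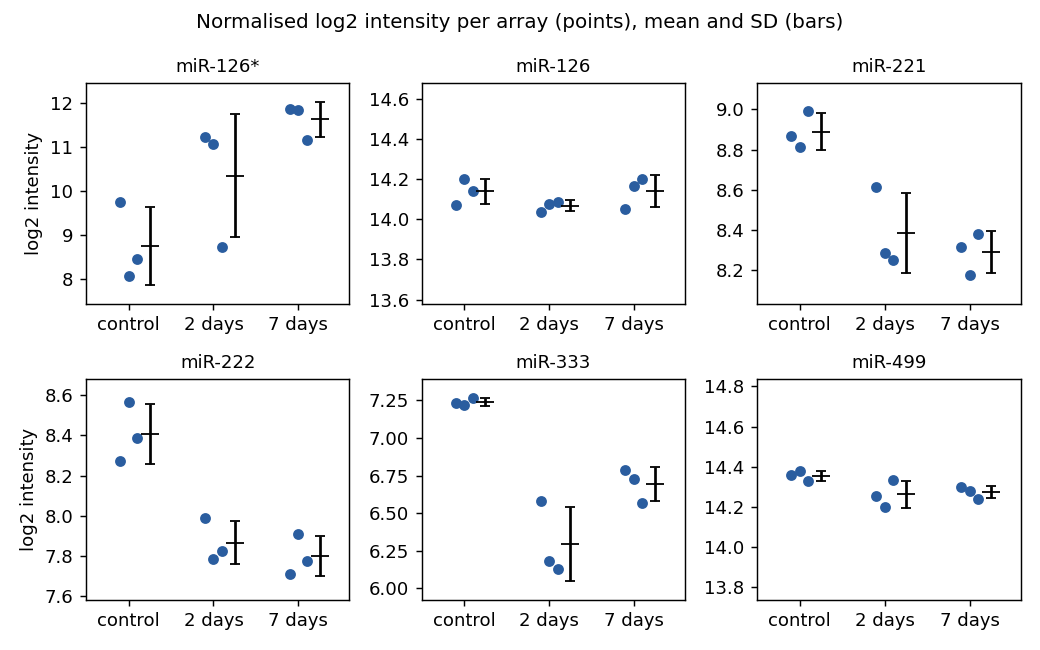
Normalised log2 intensity (y axis) of 6 miRNAs on each array (points), by group (x axis), with the group mean and SD as bars to the right of the points. MiR-221, miR-222 and miR-333 were lower on all 6 suspended arrays than on all 3 control arrays, whereas miR-126* lay at 8.74 on 2-day array 3, within the control range of 8.07 to 9.76; y axes differ between panels and do not start at 0.

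Further miRNAs among the 10 smallest p-values at 7 days were miR-189 (0.54 ± 0.15), miR-338 (0.46 ± 0.13), miR-26b (0.35 ± 0.11), miR-139 (0.55 ± 0.17) and miR-450 (0.51 ± 0.17), with adjusted p-values of 0.191 to 0.27. Over the alternatives miR-338 ran from 0.06 with 75th percentile centring (0.08 with median centring) to 2.57 in the authors' value table, and miR-189 from 0.33 to 1.13. The count of calls depended on the fit. With only the control and 7-day arrays it was 5 (miR-126* and miR-148b with higher values, miR-221, miR-222 and miR-333 with lower ones), with array weights 10, without normalisation 10, 2 in the authors' value table (miR-221 and miR-222), and with median or 75th percentile centring 1 (miR-126*). Leaving out 2-day array 1, which enters only through the shared spread, gave 3 (miR-221, miR-222 and miR-333). With only the control and 2-day arrays, limma called no miRNA at 2 days (miR-333 adjusted p = 0.132). That the main fit called miR-333 at 2 days and none at 7 days thus depends partly on fitting the groups together.

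**Figure D3:**
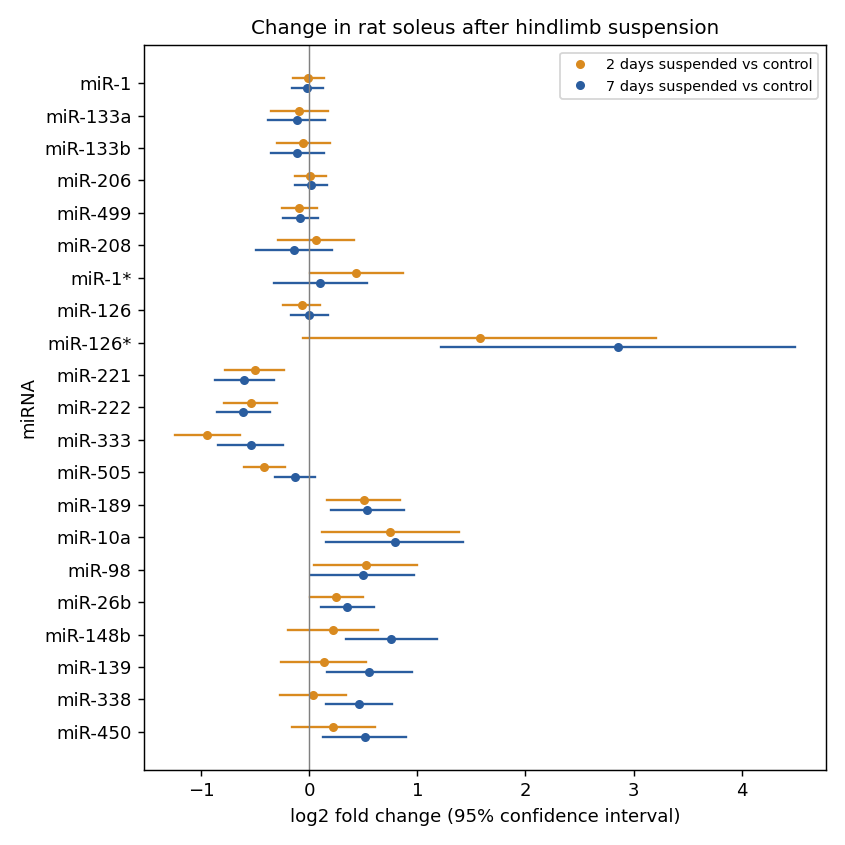
Log2 fold change against control (x axis) of 21 miRNAs after 2 days (orange) and 7 days (blue) of suspension, points with 95% confidence intervals before correction for multiple tests. MiR-1, miR-133a, miR-133b, miR-206 and miR-499 lie near 0, miR-221 and miR-222 lie near -0.6 at 7 days, and miR-126* lies at 1.58 and 2.86.

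By list at 7 days, camera called none (smallest adjusted p = 0.404) and had 1 list at an unadjusted p under 0.05, the miR-17 to miR-92 clusters, with 7 of 9 members lower and a median of -0.22. MiR-20a in it stood at -0.42 ± 0.16. Without control array 1 that list was called lower at the preset correlation (adjusted p = 0.0273) but not at the estimated one (adjusted p = 0.716, and 0.64 with all arrays). In the endothelial list 3 of 6 members had higher and 3 lower values, and miR-126*, miR-221 and miR-222 passed when adjusted over the list alone. Its median was -0.02 and its mean 0.27, with camera's direction downward. In the myoblast list miR-221 and miR-222 passed when adjusted over the list alone, while miR-450 stood at 0.51 ± 0.17, so that its median was 0.06 and its mean -0.01. Fry's test in either direction called the myoblast list (adjusted p = 1.64e-06) and the endothelial list (adjusted p = 0.000722), while camera with an estimated correlation (adjusted p = 0.973 and 0.64) and fry's one-directional test (adjusted p = 0.713 and 0.347) called neither. MiR-338 passed when adjusted over the nerve list alone, at a level near background, in a list with 2 of 5 members higher and a median of -0.03.

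The remaining lists had no member past the threshold at 7 days. The family of miR-15, miR-16, miR-103 and miR-107 had 7 of 8 members lower (median -0.08), with miR-103 at -0.45 ± 0.19 and miR-107 at -0.48 ± 0.20, which differ by 1 base. The miR-29 family, known for its collagen targets, had 3 of 4 higher (median 0.18), with miR-29b at 0.78 ± 0.33. The inflammation and fibrosis list had 5 of 5 lower (median -0.17), with miR-146 at -0.42 ± 0.14 and miR-21 at -0.17 ± 0.33. The smooth muscle and fibroblast list had 7 of 10 lower (median -0.12), with miR-145 and miR-214 at -0.52 ± 0.19 each and miR-10a at 0.79 ± 0.27. Of the blood cell markers 2 of 3 were lower (median -0.24), and miR-451 of red cells stood at -0.92 ± 0.35 and miR-223 of myeloid cells at -0.24 ± 0.42. The let-7 family (3 of 9 higher, median -0.04, let-7e 0.12 ± 0.14), the miR-30 family (6 of 6 higher, median 0.06, miR-30e 0.11 ± 0.23), the miR-23/24/27 clusters (5 of 5 lower, median -0.04, miR-24 -0.14 ± 0.09), the miR-26 and miR-181 families (3 of 5 higher, median 0.06), the epithelial and gland markers (3 of 5 higher, median 0.07, miR-205 0.14 ± 0.13) and the imprinted Dlk1-Dio3 cluster (14 of 19 lower, median -0.08, miR-494 -0.23 ± 0.09) had medians from -0.08 to 0.07. Without normalisation miR-146, miR-21, miR-223 and miR-24 stood at 0.14, 0.19, 0.18 and 0.08, miR-205 stood at -0.20 and -0.23 with the centrings, miR-223 stood at 0.28 without control array 3 and miR-30e at -0.02 without control array 2. These directions depend on the scaling, since the median of all tested miRNAs at 7 days ran from -0.23 to 0.14 over quantile normalisation, both centrings, cyclic loess and no normalisation. Set against that median, the list medians stayed above 0 under all 5 for the miR-29 family (0.21 to 0.24), the miR-30 family (0.09 to 0.15), the miR-26 and miR-181 families (0.06 to 0.10) and the epithelial and gland markers (0.01 to 0.10). They stayed below 0 for the miR-17 to miR-92 clusters (-0.19 to -0.12), the Dlk1-Dio3 cluster (-0.15 to -0.04), the striated muscle miRNAs (-0.10 to -0.05), the inflammation and fibrosis list (-0.14 to -0.03) and the miR-23/24/27 clusters (-0.03 to -0.01), and the other 7 lists reached 0 or took both signs. Both centrings and no normalisation differ only by a constant per array, so their relative medians are the same by construction. Agreement under all 5 is therefore fewer than 5 separate checks. The relative medians carry no error, and those as small as 0.01 do not establish a shift.

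Between 7 and 2 days of suspension limma called 0 of 178 miRNAs, with 10 at an unadjusted p under 0.05, all with higher values at 7 days, where 8.9 would be passed by chance. Both count and direction depended on the setting: 1 of 26 was higher with median centring, 1 of 21 with 75th percentile centring, 16 of 27 with array weights, 18 of 29 without 2-day array 1, 6 of 6 without 7-day array 2, and 4 of 5 in the authors' value table (4 of 4 there with a pseudocount of 50). The 10 were led by miR-7* (0.46 ± 0.13), miR-505 (0.28 ± 0.08), miR-489, which is known from muscle stem cells (0.50 ± 0.15), miR-338 (0.42 ± 0.13) and miR-333 (0.40 ± 0.13), each at an adjusted p of 0.392. The others were miR-350 (0.33 ± 0.11), miR-542-3p (0.21 ± 0.07), miR-148b (0.54 ± 0.18), miR-183 (0.47 ± 0.17) and miR-139 (0.42 ± 0.17). Median centring moved the median of all tested miRNAs from 0.02 to -0.15; miR-338 and miR-542-3p then stood at -0.07 and -0.27, which is 0.08 and -0.12 relative to that median. Over the alternatives miR-333 ran from 0.02 and miR-183 from 0.08, both with median centring, to 1.21 and 1.17 in the authors' value table, where miR-338 stood at 1.1 and miR-489 at 1.05. No list was called (smallest camera adjusted p = 0.256, with 3 lists at an unadjusted p under 0.05: myoblast, smooth muscle and fibroblast, and nerve). The medians of these were 0.14, -0.08 and 0.15, and relative to the median of all tested miRNAs they ran over the 5 scalings from -0.07 to 0.12, from -0.10 to 0.05 and from 0.13 to 0.35. The other 13 lists had adjusted p-values from 0.402 to 0.922, and miR-338 and miR-7* passed when adjusted over the nerve list alone. The muscle miRNAs miR-1, miR-133a, miR-133b, miR-206 and miR-499 stood between -0.06 and 0.01, miR-208 at -0.21 ± 0.15 and miR-1* at -0.33 ± 0.19, and with median centring miR-208 and miR-1* stood at -0.60 and -0.80, or -0.45 and -0.65 relative to all tested miRNAs. Both lay near background, and miR-208 was detected on no 2-day array, so their values are differences of near-background signals. Without 2-day array 3 camera called the let-7 family lower and the miR-29 family higher, and without 2-day array 2 the Dlk1-Dio3 cluster lower, but with an estimated correlation none of the 3 passed (adjusted p = 0.827, 0.827 and 0.762).

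The moderated F test over both suspension contrasts called 0 of 178 miRNAs, with 20 at an unadjusted p under 0.05, and miR-333 had the smallest adjusted p (0.0565). The count of 20 became 9 without 7-day array 2, 10 without 7-day array 1, 13 without control array 3 and 38 with array weights, and calls were made with array weights (6), without normalisation (4), without 2-day array 1 (3), in the authors' value table (2), over probes detected on all 9 arrays (1) and with the GC trend removed (1). Across miRNAs, which are not independent replicates, the 2-day and 7-day log2 fold changes had a Pearson correlation of 0.654 and a Spearman correlation of 0.601, and 127 of 178 had the same sign. Both share the 3 control arrays. Over 10000 simulations of unchanged groups against shared controls the median correlation was 0.557, with 95% of values between -0.534 and 0.954, so the observed value lay within what shared controls give. The covariance was 0.0691 against a simulated mean of 0.036, and the same central range of simulated values ended at 0.15. Both values lay within the simulated ranges, so no excess over what shared controls give is shown. Controls were too few to split. Without miR-126* the Pearson correlation was 0.564.

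Some probes were detected on all 3 arrays of the 7-day group and on no array of another group. Against control these were miR-190 and the predicted MM_89, and against 2 days miR-130b, miR-187, miR-200c, miR-208, miR-542-5p and the predicted Mmj_4 and Mmj_156. Their signals lay at the edge of background. No lower limit of a fold is given for them, because their means in the 7-day group did not exceed the mean, over the other group's arrays, of the lowest detected signal or the probe's own if higher, except for Mmj_4 with 7-day array 2 (mean log2 6.29 against 6.13, and 6.07 without that array). The log2 fold changes of miR-208 given above follow from the naming rule for the striated muscle list. They are differences of signals near background.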

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

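The alternatives with GC content, nec, the pseudocount of 50, or control 1 and 2-day 2 left out together were chosen only after the result was seen. Of 1940 values of 44 single miRNAs over the alternatives, 1818 kept their direction and side of the threshold, 37 newly passed it, 11 (miR-333 at 2 days) no longer did and 74 turned their sign, 63 of these being values no larger than their standard error and not past the threshold. MiR-333 at 2 days kept its direction in all 28 alternatives (-2.08 to -0.72) and passed in 17 (adjusted p 0.00104 to 0.521). At 7 days miR-221 (-0.73 to -0.25), miR-222 (-0.79 to -0.30) and miR-126* (2.51 to 6.41) kept theirs, each passing in 5 of 28. Signal over background limits dim probes, and the median of all tested miRNAs at 7 days moved from -0.03 to -0.21 with median centring, -0.23 with 75th percentile centring and 0.14 without normalisation, and between 7 and 2 days from 0.02 to -0.15, -0.13 and 0.12.

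Counts of calls at 2 days, at 7 days, between them and in any group were 1, 0, 0 and 0. They became 0, 1, 0 and 0 with median centring and with 75th percentile centring, 0, 10, 0 and 4 without normalisation (1 list between 7 and 2 days), and 1, 2, 0 and 2 in the authors' value table, also with a pseudocount of 50. With no detection filter they were 2, 0, 0 and 0 (4 lists at 2 days, 1 between 7 and 2 days, with more members tested), over probes detected on all 9 arrays 1, 0, 0 and 1, and by the unmoderated equal-variance test 2, 0, 0 and 0 after Benjamini-Hochberg and 5, 4, 2 and 6 at an unadjusted p under 0.01. With only the 6 arrays compared they were 0, 5 and 0, with array weights 4, 10, 0 and 6, with the GC trend removed 1, 0, 0 and 1 (1 list between 7 and 2 days), and without control 1 and 2-day 2 together 0, 0, 0 and 0 (1 list in each comparison). No list called in these settings or without 1 array passed with an estimated correlation (adjusted p 0.287 to 0.895). Fry in either direction called 2 lists at 2 days and 2 at 7 days. The other backgrounds, cyclic loess, the median of repeat spots and eBayes with trend gave 1, 0, 0 and 0 and no list. Leaving out 1 array gave 0 to 4 calls at 2 days (4 without 2-day array 1), 0 to 3 at 7 days and 0 to 3 in any group (3 without 2-day array 1 in both), 0 between 7 and 2 days, and 0 to 3 lists at 2 days, 0 to 1 at 7 days and 0 to 2 between 7 and 2 days. At an unadjusted p under 0.05 the counts ran over the alternatives from 7 to 22 at 2 days, 10 to 36 at 7 days, 4 to 29 between them and 9 to 38 in any group, beside 12, 25, 10 and 20. Where counts moved without fewer arrays or other probes, the cause was not tested.

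Replicate numbers did not pair the arrays: deviations from group means correlated between same-numbered arrays at -0.40 to 0.35, and 3 of 9 arrays were most alike to an array of their own number. With the replicate block the counts stayed 1, 0, 0 and 0, with 0 lists. No batch block was run, since the files used name no batch. Detected probes at the 99th percentile of empty spots differed by -11.0, 15.3 and 26.3 in place of -8.7, 22.7 and 31.3, and leaving out 1 array gave -16.5 to -2.0, 15.7 to 29.2 and 24.7 to 39.2. The correlation of the 2-day and 7-day changes was 0.54 with median centring, 0.78 over probes detected on all 9 arrays and 0.42 to 0.72 without 1 array.

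Signs turned as follows, none past the threshold; most concern values smaller than their standard error, and those with either centring or without normalisation include the shift of all tested miRNAs given above. With median centring the values were miR-1* -0.27, miR-206 -0.30, miR-126 -0.18 and miR-205 -0.20 at 7 days, miR-206 -0.07 at 2 days, miR-206 -0.22, miR-499 -0.13, miR-338 -0.07 and miR-542-3p -0.27 between times. With 75th percentile centring the values were miR-1* -0.29, miR-206 -0.32, miR-126 -0.21 and miR-205 -0.23 at 7 days, miR-206 -0.12 at 2 days, miR-206 -0.20, miR-499 -0.11, miR-338 -0.05 and miR-542-3p -0.25 between times. With cyclic loess the values were miR-1 0.00 at 2 days, miR-206 -0.07 and miR-126 -0.03 at 7 days, miR-206 -0.11 and miR-499 -0.04 between times. Without normalisation the values were miR-1 0.02, miR-133a 0.11 and miR-133b 0.11 between times, miR-133a 0.04, miR-133b 0.02, miR-499 0.06, miR-146 0.14, miR-21 0.19, miR-223 0.18 and miR-24 0.08 at 7 days. In the authors' value table the values were miR-1 0.06 and miR-133b 0.03 between times, miR-206 -0.06 at 2 days, miR-126 -0.01 at 7 days. With its pseudocount of 50 the values were miR-1 0.06 and miR-133b 0.03 between times, miR-206 -0.06 at 2 days, miR-126 -0.01 at 7 days. With the median of repeat spots the values were miR-206 0.00 and miR-208 -0.11 at 2 days. With array weights the values were miR-133a 0.00, miR-133b 0.04 and miR-208 -0.02 at 2 days, miR-126 -0.02 at 7 days. With the GC trend removed the values were miR-1 0.02 at 2 days, miR-133a 0.05, miR-206 -0.01 and miR-499 -0.14 between times, miR-206 0.00 and miR-126 -0.04 at 7 days. Without control 1 and 2-day 2 the values were miR-133a 0.01 and miR-499 -0.02 between times, miR-126 -0.03 at 7 days. Leaving out 1 array, ranges that crossed or reached 0 were miR-126 -0.03 to 0.05, miR-30e -0.02 to 0.26, miR-1* 0.00 to 0.27, miR-223 -0.63 to 0.28 at 7 days, miR-133a -0.17 to 0.02, miR-133b -0.13 to 0.05, miR-208 -0.11 to 0.20 at 2 days, miR-133a -0.13 to 0.06, miR-499 -0.02 to 0.05, miR-133b -0.16 to 0.01, miR-1 -0.02 to 0.00, miR-206 0.00 to 0.02 between times.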

Other observations

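The tests of repeat spots, of miR-126 against endothelial cells, of the variance between groups, of GC content for the first component and of other splits at the adjusted threshold were chosen only after the result was seen, as were the bright probes without miR-126* and the alternatives with the GC trend removed.

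Ribosomal 5S RNA was measured by 6 control probes that entered no comparison. Their mean log2 intensity was 12.66 in controls, 12.92 after 2 days and 12.88 after 7 days, with control array 1 lowest at 12.06. Single probes moved in opposite directions. From control to 2 days, probe b1 went from 10.67 to 11.75 and probe b5 from 13.32 to 12.64. Among the tested miRNAs, the 7-day change went with the GC content of the target, with a Spearman correlation across 178 miRNAs of -0.25 at 7 days against control, -0.36 at 7 days against 2 days and 0.04 at 2 days. The authors' value table gives the lowest value, 1, to miR-126* on control array 1, where the median of its 9 scanner spots was 923 against an empty-spot 95th percentile of 43. No other value of 1 in that table stood over a scanner median above 3 times that limit. In that table the log2 fold change of miR-126* at 7 days was 6.41.

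The first principal component, with 33.5% of the variance, spread arrays within groups more than between them: 5.5% of its variance lay between the 3 groups (exact permutation p = 0.85), which argues against suspension as its source. With each array's linear GC trend removed, a first component held 34.0% of the remaining variance. How much variance the removal took was not examined. The first component still ordered the arrays much as before (absolute Spearman rho 0.95), which argues against a linear GC trend as its main source. It went with the median of the empty spots over the 9 arrays (Pearson r = -0.78, exact permutation p = 0.0108; Spearman rho = -0.87, exact permutation p = 0.00451), but r was -0.49 without the 2 arrays farthest from the median, so the relation rests partly on those. A background that weighs on dim probes may be the source, but its test stays undecided: the first component over 64 bright probes had a Spearman rho of 0.22 with that over all probes, which as planned would have spoken for background, yet miR-126* alone had a loading of 0.87 there, and over the other 63 rho was 0.83, which would have spoken against it. Background level and another difference between arrays cannot be told apart here, because 1 probe decided the outcome.

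MiR-126* had higher values on each 7-day array than on each control array, by 2.86 ± 0.70 log2 units. MiR-126 from the same hairpin stood at 0.00 ± 0.08, and from -0.21 to 0.17 over the alternatives. The linear GC trend across probes did not account for the change of miR-126*, which was 2.77 ± 0.67 with that trend removed. Other effects of GC content on this probe were not tested. Noise among repeat spots stays undecided, since an absence of overlap sets separate arrays against spot noise. In scanner brightness the 7-day spots ran from 2639 to 5815 and the control spots from 128 to 1973, the lowest 7-day spot being 1.34 times the highest control spot. The 9 spots of control array 1 alone ran from 227 to 1973, so its level is less sure. Variation between arrays or samples stays open, since spots of separate arrays cannot decide it. Limma's adjusted p for miR-126* was 0.138 and passed the threshold in 5 of 28 alternatives, from 0.0124 to 0.428 over all of them. A change in which arm of the hairpin is kept, or in what else binds this probe, was not tested and stays open, as does an effect of suspension, which may differ between arrays given 8.74 on 2-day array 3 beside 11.06 and 11.23 on the others.

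The mean log2 fold change of miR-221 and miR-222 at 7 days was -0.60 ± 0.08, and both were lower on all 6 suspended arrays than on all 3 control arrays; limma's adjusted p-values, 0.0874 and 0.0946, did not pass. Fewer endothelial cells, which hold much miR-126, would lower miR-126 by about as much. MiR-126 minus the pair within arrays, where a common scaling cancels, would then stay level. At 7 days it rose by 0.45 ± 0.12 (SE) without normalisation, from 5.61 ± 0.17 to 6.06 ± 0.13 (SD, n = 3 each). There miR-126 changed by 0.17 and the pair by -0.28. With quantile normalisation, which compresses bright probes, the difference rose by 0.61 ± 0.03 (exact permutation p = 0.1, the smallest possible). The pair was picked for its fall on these arrays, which favours such a rise. These values speak against an equal fall in measured signal. A flatter response of bright probes would also give them, so fewer endothelial cells are not excluded. At 2 days miR-126 minus the pair rose by 0.26 ± 0.22 without normalisation, within 2 standard errors, and by 0.45 ± 0.10 with quantile normalisation. The 95% interval of miR-126 alone at 7 days decides nothing. That interval ended at -0.17 with quantile normalisation but at -0.71 with median centring, below the pair's -0.63 there. The linear GC trend across probes did not account for the pair's change, which was -0.57 ± 0.09 with that trend removed. Other effects of GC content on these probes were not tested. What stays open is a lower level in muscle cells or their precursors under suspension, a hypothesis these arrays of whole muscle did not test. Fewer endothelial cells with a flatter response of bright probes such as miR-126 also stay open, since no calibration was used here.

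Chance in how arrays fell into groups was tested by other splits. For 2 days against control, 3 of the 10 splits of the 6 arrays gave as many calls (1, and the highest other split 1). With 10 splits no share under 0.05 can be had. For 7 days against control all 10 gave as many (0, highest other 0), for 7 against 2 days all 10 (0, highest other 1) and for any group all 100 drawn splits of the 9 arrays (0, highest other 1), which any data would give beside a count of 0, so these 3 say nothing about chance. For the 20 miRNAs at an unadjusted p under 0.05 in any group (9 without 7-day array 2, 10 without 7-day array 1 and 13 without control array 3), 11 of 100 splits gave as many (highest other 41), so chance is not excluded for that count. At an unadjusted p under 0.05, other splits of the 6 arrays reached 47 miRNAs against 12 for 2 days against control (22 without 2-day array 1, 19 without 2-day array 3) and 39 against 10 for 7 against 2 days (29 without 2-day array 1, 6 without 7-day array 2), and what gave these counts was not tested. For 7 days against control the real split had 25 (10 without 7-day array 2, 14 without 7-day array 1, 15 without control array 1 and 16 without control array 2) and the highest other 9.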
